A study of Mus musculus with 9 samples.

How the data were processed

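Total RNA from 9 samples was labelled with a 3' in vitro transcription kit and hybridised to Affymetrix mouse arrays, per the labels' protocols. The deposited values are array intensity values, MAS5 signals on a linear scale per the submitters' processing notes; the version of MAS5 and its scaling target are not given in the sources used here. On every deposited array the mean after trimming 2% from each end was 500, and the median signal lay between 56.3 and 68.7. The table held 45101 probe sets, of which 64 were controls and were left out. Of the other 45037, 34945 carried 1 gene symbol in the platform annotation, 932 several and 9160 none, and genes were named only from the first kind; 34741 of these matched a RefSeq table of assembly GRCm38.p6 by gene identifier, with 0 symbols changed. That table was used for names, chromosomes and gene order only. Of 14 genes that were to be named whatever their values, 3 had no probe set with that single symbol here and were not analysed.

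Signals were transformed as log2(signal + 25), the offset being 5% of the trimmed mean, so fold changes are on that scale and understate changes of dim probe sets. A probe set was tested when its mean over the 9 arrays was at least 100, which left 19090 probe sets and 10177 genes. All arrays entered a single fit in limma 3.58.1 (R 4.3.3) with 5 group means, 4 residual degrees of freedom and an intensity trend in the moderated variance. P-values were adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05, and all p-values are two-sided. Groups of 1 array were assumed to vary like the others. Where a gene had several probe sets, the one with the highest mean signal was used. Other tested probe sets are given singly only for Kmt5b, Xist and Cdkn1a. For the other called genes, second probe sets were only counted together.

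Gene lists (33, including markers of other cell types; 1 of them is not reported here) were tested with camera in limma on 1 probe set per gene, with a preset correlation between genes of 0.01 and with an estimated one, adjusted over lists. Counts of members are given over all probe sets and adjusted over the list alone. The genes named per comparison were the 10 highest and 10 lowest log2 changes among passing genes with non-overlapping groups and a brighter-group mean of at least 200; with fewer than 5 passing, those that passed and then the smallest p under the same conditions, up to 5 each way. In each list up to 4 passing members with the largest changes were named. The groups, comparisons, lists, naming rule and most alternatives were fixed before the data were examined.

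The reversal analysis computed the line difference and the reconstitution change from non-overlapping null arrays, beside simulated unchanged groups. Alternatives were other offsets (5 and 100), no filter or a minimum of 200, quantile normalization, no intensity trend, the compared groups alone, each replicate left out, other groupings of arrays, and, chosen after seeing the data, the wild-type GFP and K278* arrays left out, the mean of the cell-cycle lists as a covariate, list shifts with each array left out, and reversal over calls made without the other null array. The procedure was tested on simulated data of the same design with 50 probe sets changed at each fold: 2-fold changes were recovered in 64% of cases for truncated PREX2 against control vector, 36% for full-length PREX2, 28% for truncated against full-length, 48% for the null line and 30% for reconstitution, with 7 to 15 false calls. At 4-fold, recovery was 86% to 100%. The simulated noise had the same spread in every group, which the real arrays did not, so recovery in the data may be lower.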

Results

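Gene expression was measured with 9 Affymetrix mouse arrays in 2 spontaneously immortalised lines of mouse embryonic fibroblasts, connective-tissue cells taken from embryos. The first line came from embryos lacking Suv420h1 (gene symbol Kmt5b), an enzyme that methylates histone H4. It was measured untransduced, with GFP, and with a Suv420h1-GFP fusion protein. The second line was wild type and was transduced with lentivirus to express GFP, LacZ, full-length PREX2, or PREX2 ending at a stop codon (K278*, E824* or Q1430*). PREX2 is an exchange factor for the GTPase Rac. The groups were the Suv420h1-null line (2 arrays), the reconstituted null line (1), wild-type control vector (2, GFP and LacZ), full-length PREX2 (1) and truncated PREX2 (3). The number of arrays limits the precision of every comparison. Within a group no construct was repeated, and nothing in the labels says that arrays of a group came from separate cultures, so p-values measure only the spread between these arrays.

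Line was the largest source of variation. The first principal component held 69.6% of the variance and placed the null-line arrays between -71.6 and -68.3 and the wild-type-line arrays at 28.4 or above. The second held 17.8% and separated wild-type arrays from each other, with GFP at -59.6, K278* at -19.4, full-length PREX2 at 3.82, LacZ at 15.7, Q1430* at 22.0 and E824* at 30.7. The GFP and LacZ arrays, which form the control group, differed by more than 2-fold at 1301 probe sets, whereas LacZ and Q1430* differed at 65 and the untransduced and GFP null arrays at 81.

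**Figure D1:**
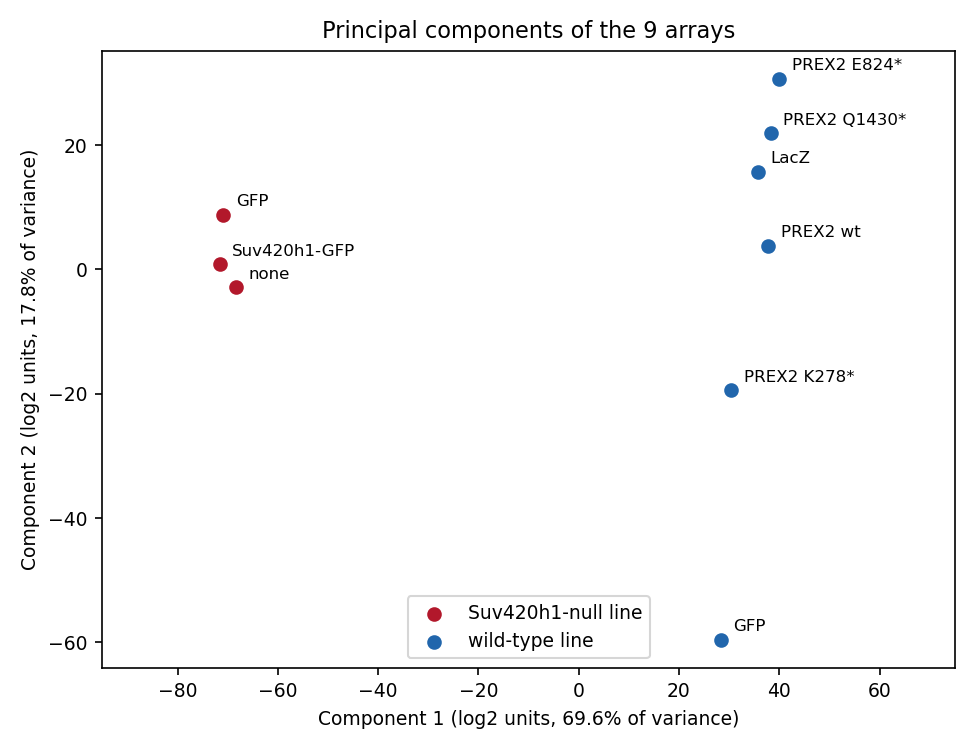
The first and second principal components of log2 signal over 19090 probe sets are plotted, with each point an array named by its construct and coloured by line. The null-line arrays lie at -68.3 or below on the first component, and the wild-type GFP array lies at -59.6 on the second, below all other arrays.

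The targeted gene was examined first. The brightest of 4 tested Kmt5b probe sets (mean signal 411) read 442 and 432 on the null arrays and 295 and 469.6 on the control-vector arrays, a log2 difference of 0.22 (SE 0.22, 2 against 2 arrays, adjusted p = 0.528), which was -0.10 without the GFP control array. Another, with a mean signal of 117.5 and singled out after its values were seen, read 8.85 and 17.3 on the null arrays, 150.3 on the reconstituted array and between 118 and 182 on the wild-type-line arrays. Its log2 change in the null line was -2.05 (SE 0.231, adjusted p = 0.0015), and its difference on reconstitution was 2.21 (SE 0.282, 1 against 2 arrays), which did not pass (adjusted p = 0.492). Of the remaining probe sets, that with a mean signal of 116 differed by -0.51 (adjusted p = 0.175), and that with a mean of 365 rose by 0.81 (SE 0.217, adjusted p = 0.0398), a call that ended with either null array left out and without the GFP control array (0.53). The part of the transcript that each probe set reads is not given in the sources used here, so a probe set outside the deleted part would check nothing. Kmt5c (Suv420h2), the paralogous enzyme, differed between the lines by -0.11 (SE 0.193, adjusted p = 0.722).

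The comparison of the null line with wild-type control vector asks which transcripts differ where Suv420h1 is missing. In the null line the cell-cycle inhibitors Cdkn2a and Cdkn2b were high, with mean signals of 3836 and 1653 against 10.1 and 4.17 in control-vector cells (log2 changes of 6.79, SE 0.236, and 5.84, SE 0.207, 2 against 2 arrays). The secreted protein C1qtnf3 was 275-fold higher (log2 8.10, SE 0.173), and the matrix protein Efemp1 fell by 8.83 (SE 0.233), from 20773 to 22.0. The dim sides of Cdkn2a, Cdkn2b and Efemp1 lay under the offset of 25, so the size of these log2 changes depends on it (8.10, 7.50 and -9.72 with an offset of 5). Of 35 interferon-stimulated genes 30 rose, and of 25 ERK-output and immediate-early genes 11 rose, among them Fos and Egr1; neither list's shift passed with an estimated correlation (adjusted p = 0.725 for both). In all, 2047 probe sets rose and 1706 fell, out of 19090, in limma at an adjusted p below 0.05; these belonged to 1330 and 1196 genes, and 1766 changed by more than 2-fold. Without the untransduced null array 1226 probe sets passed, and without the GFP null array 1011; without the latter 17 interferon-stimulated and 7 ERK-output genes rose.

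The other genes with the largest increases on this scale were the homeobox gene Hoxc8 (log2 6.78), the Wnt-binding protein Sfrp2 (6.43), the fibrillar collagen Col11a1 (6.36), the prelamin protease Zmpste24 (6.32), the cysteine dioxygenase Cdo1 (6.13), Itm2a (6.11) and Plac8 (6.06), with adjusted p between 9.95e-06 and 0.000112. Control signals of several were near background (2.47 for Hoxc8), so the offset sets their order: with an offset of 5, Hoxc8 was at 8.66 and C1qtnf3 at 8.58. After Efemp1, the largest decreases on this scale were in the interferon-inducible Ifi202b (-6.15, SE 0.136), 3110039M20Rik (-5.78), the fibroblast surface protein Thy1 (-5.47, SE 0.450), Gm6958 (-5.01) and the neuropeptide gene Vip (-4.64, SE 0.750). Ifitm1 (-4.28), Akr1c13 (-4.15), the ATP-gated channel P2rx3 (-3.81) and the GDNF-family receptor Gfra2 (-3.72) followed. The null-line signals of Ifi202b (3.24), 3110039M20Rik (17.6), Thy1 (19.3), Gm6958 (15.4) and Akr1c13 (6.86) lay under the offset of 25, which therefore sets the size and order of these decreases: with an offset of 5, Ifi202b was at -7.92 and Akr1c13, at -5.55, ahead of Vip (-4.93), and with an offset of 100 Gm6958 (-3.52) was behind Vip (-3.96). The call of Vip ended without the GFP null array (-3.80) and that of P2rx3 without the untransduced array (-3.53).

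**Figure D2:**
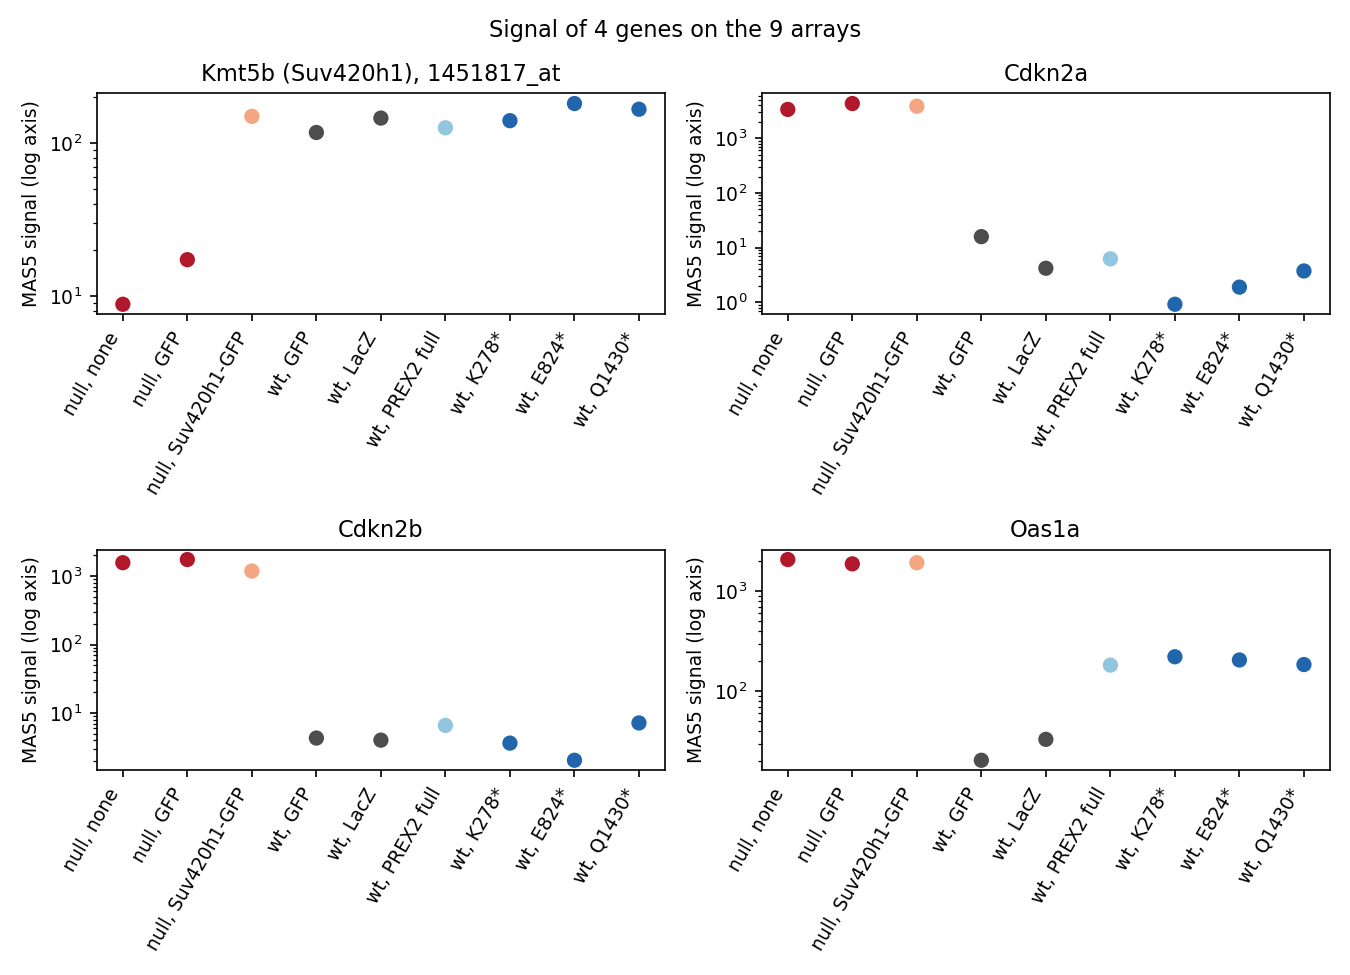
Each point is the deposited signal of a probe set on an array, on a log axis, for Kmt5b (the probe set with a mean signal of 117.5), Cdkn2a, Cdkn2b and Oas1a, with null-line arrays in red tones and wild-type-line arrays in grey and blue. Cdkn2a lies between 3363 and 4308 on the null-line arrays and at 15.9 or below on the wild-type-line arrays.

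Of 35 interferon-stimulated genes measured, 30 rose, 1 fell and 4 did not pass, and 33 rose and 1 fell adjusted over the list alone. The median log2 change was 2.30. Oas1a, which makes an activator of RNase L, rose by 5.28 (SE 0.181), the deubiquitinase Usp18 by 5.08 (SE 0.518), Rtp4 by 4.42 (SE 0.497) and the virus-tethering protein Bst2 by 3.69 (SE 0.470). The member that fell was the chemokine Ccl5 (-1.15, adjusted p = 0.015), named after its value was seen. Without the GFP null array 17 rose and Ccl5 did not pass. The shift of the list passed with a preset correlation (adjusted p = 1.47e-17) and not with an estimated one (adjusted p = 0.725 with an estimated correlation). The wild-type GFP array had the lowest mean of this list, 7.47, against 8.48 on LacZ and 10.3 to 10.6 in the null line.

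Among ERK-output and immediate-early genes, 11 of 25 rose and 0 fell, also adjusted over the list alone. Fos rose 47.0-fold (log2 5.56, SE 0.339), Egr1 20.4-fold (4.35, SE 0.229), Ier2 by 3.44 on the log2 scale and Egr3 by 3.42. Of 30 p53 target genes, 10 rose and 0 fell, likewise adjusted over the list alone; they included Perp (4.53), Pmaip1, the apoptosis gene known as Noxa (3.72), Ddit4l (3.58) and Btg2 (3.12). Cdkn1a, another member, differed by 0.31 (SE 0.330, adjusted p = 0.546), and by 0.06 (SE 0.461, adjusted p = 0.945) at its other tested probe set. Of 27 imprinted genes, 12 rose and 2 fell, and 12 rose and 5 fell adjusted over the list alone; Peg3 rose by 4.59 (SE 0.480), Dlk1, a Notch-ligand-like protein, by 4.27, Asb4 by 2.80 and Plagl1 by 2.72 (SE 0.689). The shifts of these 3 lists passed with a preset correlation (adjusted p = 2e-06, 2e-06 and 0.01). None passed otherwise (adjusted p = 0.725, 0.572 and 0.725 with an estimated correlation). Without the wild-type GFP array the median of imprinted genes went from 0.62 to 0.27, that shift did not pass, and Plagl1, at 1.74, lost its call. Without the GFP null array 7 ERK-output, 6 p53-target and 5 imprinted genes rose, and without the untransduced array 11, 6 and 7; Plagl1 did not pass in either case, nor Asb4 (2.18) in the first. Of the wild-type-line arrays, GFP had the highest mean of the ERK-output list, 9.72 against 8.85 on LacZ, and the lowest of the imprinted list, 9.57 against 10.3.

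Fewer lists fell. In the mitochondrial respiratory chain 9 of 31 genes fell and 1 rose, and 16 fell and 1 rose adjusted over the list alone; Cyc1 was at -0.88, Ndufs1 at -0.79 and Sdhb at -0.77, whereas Cox7c rose by 0.88. Of 24 cytosolic ribosomal protein genes 4 fell and 1 rose, also adjusted over the list alone, with Rps3 at -0.50, Rpl22 at -0.48, Rps19 at -0.46 and Rps6 at 1.38. After quantile normalization the ribosomal median moved from -0.24 to -0.06, and the respiratory median from -0.34 to -0.235. Both shifts passed with a preset correlation (adjusted p = 4.49e-05 and 0.00611) but not otherwise (adjusted p = 0.725 for both with an estimated correlation). Of 31 genes of the unfolded-protein and amino-acid response 12 fell and 0 rose, and 15 fell and 3 rose adjusted over the list alone. Nupr1 (-2.21), Atf5 (-1.67), the amino-acid transporter Slc7a5 (-1.30) and Trib3 (-1.15) fell most. The list did not shift as a whole with the preset correlation (adjusted p = 0.0583), nor with an estimated one. It did with the preset correlation without the GFP null array or the wild-type GFP array, fits with 1 array left in a group. Its mean was 11.6 on the wild-type GFP array and 11.9 on LacZ. Without the untransduced null array 3 respiratory genes and 5 of the unfolded-protein response fell, and without the GFP null array 2 and 7; without LacZ 4 of the latter list rose and 9 fell. The calls of Cyc1 (with either null array left out), Sdhb (without the GFP null array, -0.745) and Trib3 (without the untransduced array, -1.11) ended in this way. Leaving out any 1 of the 4 arrays ended the calls of Cox7c, Rps3 and Rps19, and leaving out any but LacZ ended that of Rpl22.

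Several lists moved in both directions. Over all probe sets, 2047 of 19090 rose and 1706 fell between the lines. A count near those shares, here or in the other lists, does not set a list apart. Of 33 HOX and positional-identity genes 10 rose and 13 fell, and 11 rose and 15 fell adjusted over the list alone, with Hoxc8, Hoxa9 (5.17), Hoxc10 (4.83) and Hoxa10 (4.31) highest. The median of the HOX list was -0.39, its mean 0.51 and the direction of its test higher (adjusted p = 0.978). Of 28 contractile and SRF/YAP-response genes 5 rose and 7 fell, and 7 rose and 9 fell adjusted over the list alone; Ccn1 rose 9.18-fold, while Ankrd1 (-2.96), the smooth-muscle genes Cnn1 (-2.86) and Actg2 (-2.42) fell. Of 44 matrix genes 8 rose and 3 fell, and 8 rose and 4 fell adjusted over the list alone, with Col11a1, Efemp1, Thbs2 at 3.60 and the proteoglycan Fmod at 3.14. The wild-type GFP array had the lowest matrix mean of the 9 arrays, 11.1 against 11.6 to 12.1 on the other wild-type-line arrays. Fmod read 33.7 on the GFP control array and 367 on LacZ, and its call ended without the GFP control array (1.77) and with either null array left out. Of 31 Wnt, BMP and TGF-beta genes 6 rose and 2 fell, also adjusted over the list alone, among them Sfrp2, Bmp6 (3.43), Smad7 (2.11) and Id4 (-2.03). Of 24 hypoxia and glycolysis genes 2 rose and 9 fell, also adjusted over the list alone, with Slc2a1, the glucose transporter, at -1.19, Aldoa at -1.13, Adm at 1.87 and P4ha2 at 1.06. Of 36 G1/S genes 0 passed (median -0.34), and of 35 G2/M genes 2 rose and 1 fell (Cenpe 1.17, Ccnb2 0.74, Bub3 -0.66), with 0 adjusted over the list alone. The wild-type GFP array had the highest G1/S mean of the 9 arrays, 11.3 against 10.5 on LacZ, and the lowest Wnt, BMP and TGF-beta mean, 9.76 against 10.4. Without LacZ more matrix and Wnt, BMP and TGF-beta genes rose and more G1/S genes fell than with both control arrays. The shifts of these lists and of G2/M then passed with the preset correlation, as that of G1/S did without the untransduced array. Those fits leave 1 array in a group, and with all arrays none of these lists shifted with the preset or an estimated correlation. Without the wild-type GFP array 6 Wnt, BMP and TGF-beta genes and 5 hypoxia and glycolysis genes fell. With either null array left out 7 HOX-list genes fell, and 5 matrix and 3 Wnt, BMP and TGF-beta genes rose. Of the hypoxia and glycolysis genes, 2 fell without the untransduced array and 1 without the GFP null array, and without the latter 3 contractile genes rose and 4 fell. Calls also ended for Smad7, Cenpe, Ccnb2 and Bub3 with either null array left out, for Ankrd1 (-2.77), Slc2a1 (-1.14), Adm (1.63) and P4ha2 (0.85) without the GFP null array, for Bub3 (-0.52) without the GFP control array, and for Cenpe (0.92) and Ccnb2 (0.58) without LacZ.

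Prex2 fell by 0.74 (SE 0.201, adjusted p = 0.0412). FOXO targets had 5 of 23 higher and 3 lower (Klf2 2.37, Fbxo32 -1.60, Irs2 1.41, Klf6 1.15), also adjusted over the list alone. NRF2 genes had 4 of 23 higher and 4 lower, and 4 and 7 adjusted over the list alone (Gsta3 -1.64, Hmox1 1.44, Gsr 1.38, Taldo1 -1.14). The wild-type GFP array had the highest NRF2 mean of the wild-type-line arrays, 10.98 against 10.74 on LacZ, and the lowest mean of secreted factors, 9.83 against 10.2. Secreted factors had 3 of 22 higher and 3 lower, and 5 and 3 adjusted over the list alone (Mmp3 -3.31, Lif 2.44, Ccl9 -1.35, Csf1 1.11), and adhesion molecules 7 of 29 higher and 2 lower, also adjusted over the list alone (Thy1, Cdh3 2.72, Jam2 -1.44, Pcdh19 1.33). Of 12 CDK inhibitors and immortalisation genes 2 rose and 2 fell, the latter Cdkn2c (-0.99) and Cbx8 (-0.68), also adjusted over the list alone; the median of that list was -0.05 and its mean 0.88. DNA repair had 1 of 33 higher (Nbn 0.61) and 3 lower (Rad54l -1.25, Palb2 -0.89, Xrcc6 -0.60), histone-methylation and heterochromatin factors 1 of 26 higher (Daxx 0.67) and 1 lower (Trim28 -0.50), and cholesterol synthesis 1 of 20 higher (Msmo1 0.54), with 0 in each adjusted over the list alone. Of the markers of other cell types, Pparg (1.94), Col2a1 (3.45), the endothelial gene Eng (1.44) and Perp rose, and Fabp4 (-1.65), Dgat2 (-0.92), Krt19 (-1.70), Csf1r (-0.76), Map2 (-2.41) and Tubb3 (-1.83) fell. Adjusted over the list alone, 2 endothelial genes rose and 2 macrophage genes fell, and the other marker lists kept their counts. Of 17 fibroblast markers, Thy1 and Twist2 (-1.06) fell. The mean of that list was 11.9 on the wild-type GFP array, 12.8 on LacZ, 12.3 to 12.9 on the PREX2 arrays and 11.6 to 11.9 in the null line. Its median change, -0.23 with all arrays, was -0.44 without the GFP array, 0.05 without LacZ and -0.083 after quantile normalization. The GFP array was also the lowest wild-type-line array for FOXO targets (9.63 against 10.2 on LacZ) and for adipocyte (9.07 against 9.78), endothelial (7.04 against 8.05) and neural (8.09 against 8.74) markers. Of 6 muscle markers and 3 germ-line genes 0 passed, also adjusted over the list alone. Apart from the 6 lists whose shift passed, no list shifted between the lines with the preset correlation (adjusted p of 0.0583 or above). With an estimated correlation none passed. That correlation was estimated with 4 residual degrees of freedom, and even the interferon list, most of whose genes passed singly, did not pass. Not passing this test therefore does not show that a list did not shift. With 1 array left out, chosen after seeing the data, 7 to 11 lists shifted with the preset correlation, in fits that leave 1 array in a group. With either null array left out, the calls of Prex2, Irs2, Gsta3, Taldo1, Csf1, Cbx8, Rad54l, Palb2, Xrcc6, Nbn, Daxx, Trim28, Msmo1, Dgat2, Csf1r, Map2, Tubb3 and Twist2 ended, and so did that of Cdkn2c (-0.88) without the untransduced array and those of Fbxo32 (-1.27), Jam2 (-1.34), Pcdh19 (1.22) and Krt19 (-1.42) without the GFP null array. Without the wild-type GFP array those of Rad54l, Palb2, Xrcc6 (-0.39), Nbn, Daxx, Msmo1, Irs2 and Taldo1 ended, and without LacZ those of Prex2 (-0.46), Csf1r (-0.49), Tubb3 (-1.22), Cbx8, Csf1, Nbn, Daxx, Msmo1 and Irs2. Higher and lower FOXO targets numbered 2 and 1 without the untransduced array and 2 and 0 without the GFP null array, NRF2 genes 2 and 0 and secreted factors 1 and 2 in both cases, and adhesion molecules 3 and 2, then 2 and 1. Without LacZ 10 NRF2 genes fell and 8 secreted factors rose, and without the wild-type GFP array 5 adhesion molecules fell.

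Xist, the RNA that coats the inactive X chromosome, was read by 3 probe sets, each higher in the null line (1.08, 1.67 and 2.25, adjusted p between 0.00106 and 0.00142), and was the 1 passing gene of 5 sex-linked genes tested, also adjusted over the list alone. The probe sets of the Y-linked genes Eif2s3y, Kdm5d and Uty were under the signal minimum, with means over 9 arrays of 22.5 or below. Cdkn1c was likewise not tested (mean 10.9). With only the GFP array of each line compared, 1 against 1, the changes correlated at 0.922 with those from both arrays of each group. Genotype and immortalised line go together between the null and wild-type lines, so that comparison cannot separate them. Reconstitution, with 1 array, varies Suv420h1 within the null line.

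**Figure D3:**
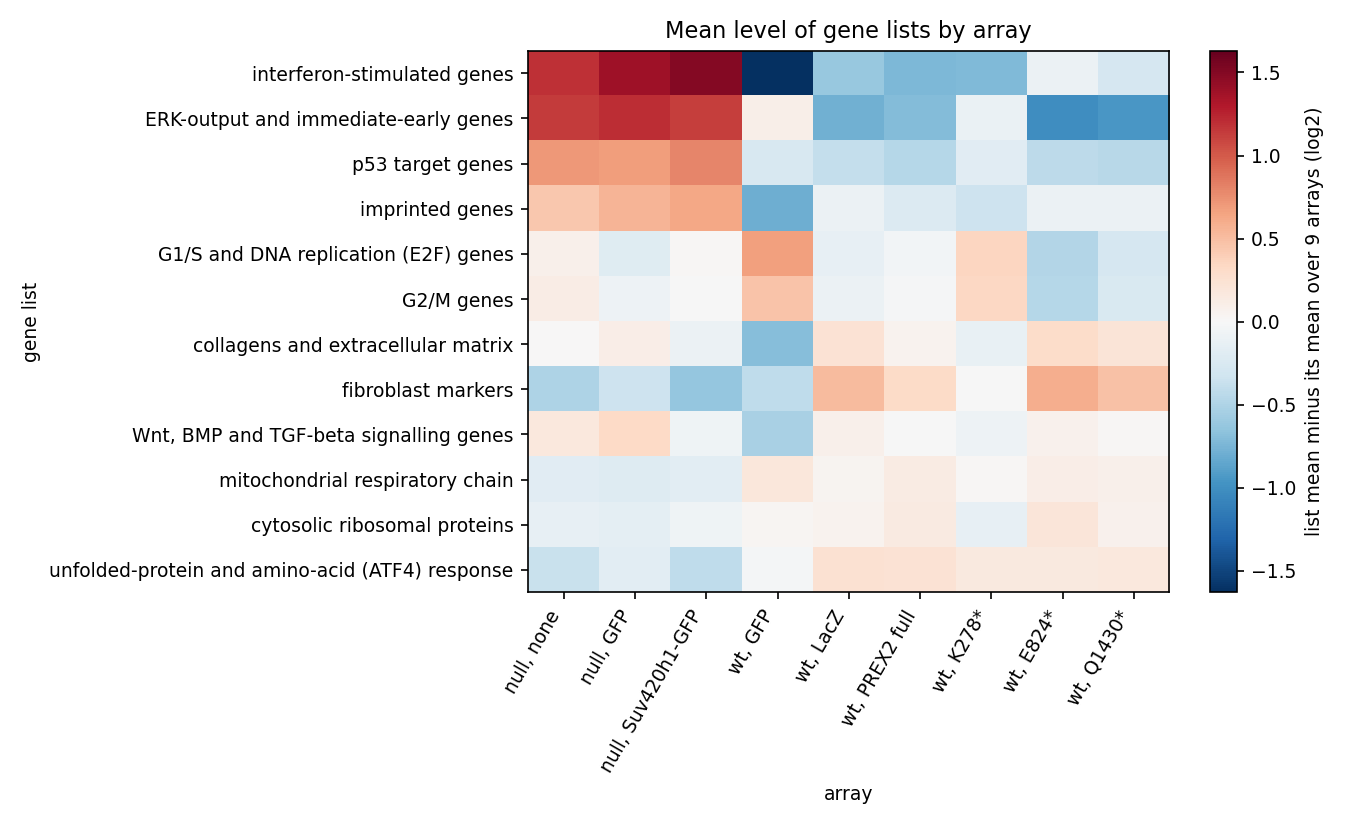
Each cell is the mean log2 signal of a gene list on an array, minus the mean of that list over the 9 arrays, with lists in rows and arrays in columns. Before that subtraction, the mean of the interferon list lies between 10.3 and 10.6 in the null line. In the wild-type line it lies between 7.47 and 9.01, and the wild-type GFP array is lowest.

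**Figure D4:**
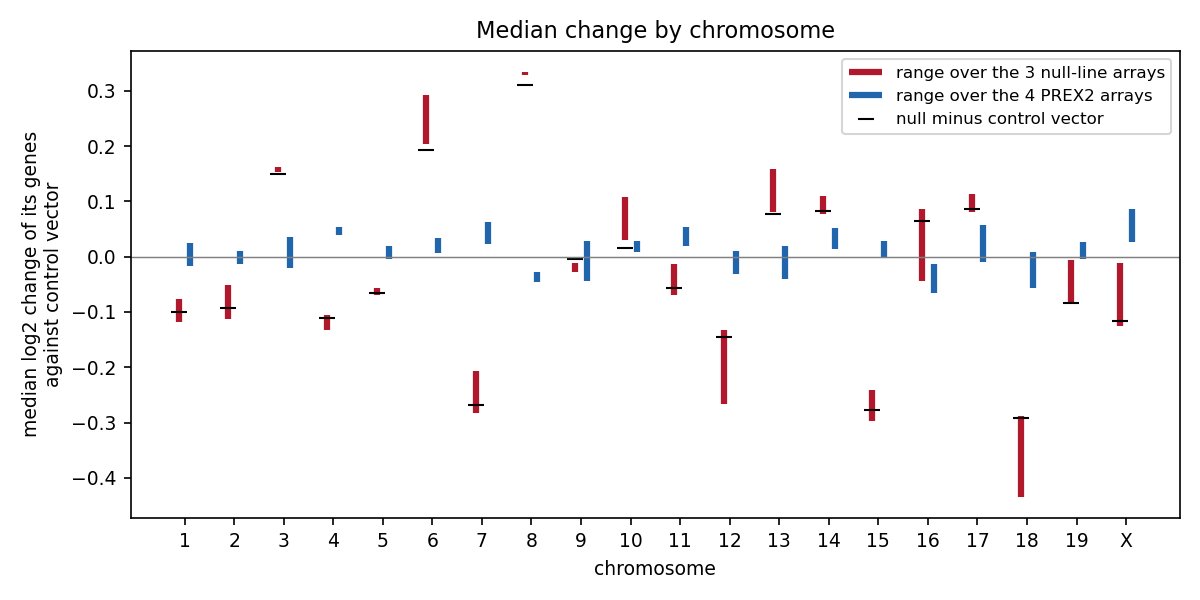
For each chromosome, the black mark is the median log2 change of its genes in the null line against control vector, and bars give the range of that median over the 3 null-line arrays (red) and the 4 PREX2 arrays (blue). Chromosome 8 lies at 0.31 and chromosome 18 at -0.29.

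The reconstituted array was set against the null arrays to ask what the fusion protein restores. The actin-binding protein Tagln had the smallest p, with a signal of 2872 against 6873 (log2 -1.25, SE 0.115, 1 against 2 arrays), and did not pass (adjusted p = 0.155). The collagen Col8a1 (-1.66, SE 0.210), Gm41724 (-0.87), the Notch-ligand gene Dner (-1.61) and Eva1b (1526 against 3079) were, of the lower genes, next by p, and of the higher genes the metallothionein Mt2 (1.79, SE 0.309), Depdc7 (1.46), Fmr1 (0.81), the fatty-acid-binding gene Fabp4 (1.21) and the chemokine Ccl5 (1.31) had the smallest p by the naming rule, none of them passing. Tagln, at 13869 and 13156 on the wild-type GFP and LacZ arrays, moved away from the control-vector mean, as did Gm41724 and Depdc7. Eva1b, Mt2 and Fmr1 passed that mean and ended farther from it than the null arrays. Col8a1, Dner, Fabp4 and Ccl5 ended closer to it. Cdkn2a differed from the null arrays by 0.02 (SE 0.289; -0.16 without the untransduced array) and Cdkn2b by -0.47 (SE 0.254, adjusted p = 1 for both). In limma 0 of 19090 probe sets passed, with 621 at an unadjusted p below 0.05 against 954.5 by chance. The spread behind these p-values was shared over all groups. It includes the wild-type GFP and LacZ arrays, which are not compared here. They differed by more than 2-fold at 1301 probe sets, against 81 for the 2 null arrays. The 0 therefore does not show that reconstitution changed nothing. Wnt, BMP and TGF-beta genes (median -0.30, preset adjusted p = 0.000139) and the unfolded-protein response (-0.14, preset adjusted p = 0.0095) shifted lower with the preset correlation only (adjusted p = 0.957 for both with an estimated correlation). Without the GFP null array the medians were -0.18 and -0.04, and the second did not pass. Members passing adjusted over the list alone were 1 lower in the matrix list, 2 lower in the contractile list and 1 higher among adipocyte markers. The lone reconstituted array was assumed to vary like the other groups, and with the spread of these 2 groups alone, from 1 residual degree of freedom, 233 probe sets passed.

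Reversal was examined across the 3753 probe sets called between the lines. With the untransduced null array behind the line difference and the GFP null array behind the reconstitution change, 57.0% went the opposite way on reconstitution (95% binomial interval 55.4 to 58.6), with r = -0.119 across probe sets and a covariance of -0.0681. With these arrays swapped the share was 51.7%, r = 0.009 and the covariance 0.00497. Unchanged simulated groups gave 50%, but over all probe sets and without selecting called ones. The calls used both null arrays, and that selection itself favours opposite signs. With calls made without the other null array, chosen after seeing the data, the share was 52.5% (interval 49.4 to 55.6), and 46.6% (43.8 to 49.4) with those arrays swapped. These shares do not show reversal. With both null arrays shared by the changes, the share was 54.9%, r = -0.089 and the covariance -0.0475. Over all 19090 probe sets the shared arrays gave r = -0.086 and a covariance of -0.0188, beside -0.407 and -0.0314 for unchanged simulated groups, in which 63.4% had opposite signs. The median size of the line difference was 0.95 on the log2 scale and that of the reconstitution change 0.19; 9.70% of these probe sets moved back by at least 50% of the line difference, and 4.05% moved as far the other way. These shares were 7.33% and 4.56% with the null arrays swapped and 6.34% and 4.05% with shared null arrays. Over probe sets called without the other null array, chosen after seeing the data, they were 2.27% and 1.29%, and 1.71% and 2.28% with those arrays swapped, which turns the direction. Probe sets are not independent replicates, and the interval covers counting only.

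Truncated PREX2 was compared with control vector to ask what the mutant proteins change. Oas1a was the only gene that passed, at 221, 206 and 185 on the truncated arrays against 20.4 and 33.1 on the control arrays (log2 2.15, SE 0.165, adjusted p = 0.0429), and it read 183 on the full-length array. Its call ended with an offset of 100 (1.26), with no filter, with the spread of these groups alone, and with full-length PREX2 added to the controls (1.48). The genes of next smallest p did not pass (adjusted p = 0.844): higher were Tmlhe (0.53), the mitochondrial ribosomal gene Mrpl33 (0.57), Zfp141 (0.63) and Mettl7a2 (1.14), and lower were the kinase gene Prkx (-0.75, SE 0.160), Fbxw22 (-0.84), Zfp64 (-0.50), Gid4 (-0.64) and the proteasome gene Psmd14 (-0.32). Prex2 itself, at the probe set tested, read 452 and 677 on the control arrays and 703 to 809 on the 4 PREX2 arrays (0.41, SE 0.184, adjusted p = 0.844). Which species the PREX2 constructs came from is not given in the sources used here, so the mouse probe set may not read them.

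Of 35 interferon-stimulated genes 1 rose, Oas1a, both over all probe sets and adjusted over the list alone, and all 35 had a positive change (median 0.73, preset adjusted p = 4.82e-16). Matrix genes (0.20) and secreted factors (0.23) also shifted higher with the preset correlation, and G1/S (-0.40), G2/M (-0.31), contractile (-0.19), DNA repair (-0.17) and ERK-output genes (-0.34) lower, with 0 members passing in each, also adjusted over the list alone. None of these 8 shifts passed otherwise (adjusted p = 0.749 with an estimated correlation). For each of these 8 lists the wild-type GFP array was the lowest (interferon, matrix, secreted factors) or highest (the other 5) of the 6 wild-type-line arrays, with interferon means of 7.47 on GFP and 8.48 on LacZ and G1/S means of 11.3 and 10.5. The interferon mean was 8.38 on K278*, below LacZ, 9.01 on E824* and 8.82 on Q1430*. List shifts without single arrays were computed after the data were seen. Without the GFP array, which leaves 1 control array, the interferon median was 0.23 (29 of 35 positive) and the contractile median -0.10. In that setting the matrix (-0.12) and ERK-output (0.08) medians turned. Those of G1/S (-0.03), G2/M (-0.04), DNA repair (-0.05) and secreted factors (0.055) shrank, and neither their shifts nor that of ERK-output passed. Without LacZ all 8 medians were larger in size (interferon 1.18, matrix 0.49, secreted factors 0.54, G1/S -0.83, G2/M -0.57, contractile -0.31, DNA repair -0.29, ERK-output -0.74). Without E824* the matrix (0.16), DNA repair (-0.10) and ERK-output (-0.21) shifts did not pass, and G1/S was at -0.22, G2/M at -0.14 and secreted factors at 0.12. Without Q1430* ERK-output genes (-0.25) did not pass, and without K278* secreted factors did not (0.23), while G1/S was at -0.665, G2/M at -0.53, ERK-output at -0.53 and DNA repair at -0.29. Without the GFP array 0 probe sets passed (Oas1a at 1.98) and the changes correlated at 0.338 with those from both control arrays; without LacZ 117 passed, and without K278*, E824* or Q1430* alone 0 passed.

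Full-length PREX2 against control vector gave 0 of 19090 probe sets in limma (1 against 2 arrays, 269 at an unadjusted p below 0.05 against 954.5 by chance). The metallothioneins Mt1 (1.01, SE 0.332) and Mt2 (0.94), Mmaa (0.66), Dhrs3 (0.63) and Fxr2 (0.83) had the smallest p of the higher genes by the naming rule, and Mideas (-0.84, SE 0.159), Gse1 (-0.98), the splicing factor Srsf4 (-0.64), Cklf (-0.69) and Casp14 (-0.83) of the lower genes, none passing (adjusted p = 1). Prex2 differed by 0.50 (SE 0.246). Of the interferon list 0 passed over all probe sets and 1 adjusted over the list alone (median 0.31). With the preset correlation 11 lists shifted, among them G1/S (-0.26) and cholesterol synthesis (0.21), and 0 with an estimated correlation (adjusted p = 0.653 for both named). These list shifts and changes share the control arrays of the truncated comparison, GFP among them. Without the GFP array, a setting chosen after seeing the data, none of the 11 shifts passed; the medians of 6 of these lists turned, G1/S (0.10) and interferon-stimulated genes (-0.10) among them, and that of cholesterol synthesis was 0.01. Without LacZ 3 probe sets passed, and the medians were -0.71 for G1/S, 0.74 for interferon-stimulated genes and 0.42 for cholesterol synthesis.

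Truncated against full-length PREX2 asks whether the stop codons matter, and gave 0 of 19090 probe sets in limma (3 against 1 arrays). At an unadjusted p below 0.05 there were 241, against 954.5 by chance. The shared spread includes the GFP and LacZ arrays, which are not compared here. The 0 therefore does not show that the stop codons change nothing. Named by smallest p, Mideas (0.69, SE 0.150), Apol7a (1.03), Cklf (0.65), the export-complex gene Thoc5 (0.68) and Zfp141 (0.76) were higher with truncated PREX2, and Wdr59 (-0.59), the adaptor subunit gene Ap2a1 (-0.64), Lims2 (-0.83), Gid4 (-0.64) and Usb1 (-0.60) lower, none passing (adjusted p = 1). With the preset correlation 6 lists shifted, among them interferon-stimulated genes (0.24) and ribosomal proteins (-0.11, but 0.01 after quantile normalization), and 0 with an estimated correlation (adjusted p = 0.976 for both). Without K278*, a setting chosen after seeing the data, the medians were 0.55 for interferon-stimulated genes and -0.01 for ribosomal proteins, whose shift did not pass; the latter was -0.18 without E824*. The G1/S and G2/M medians, -0.08 and -0.10 with all arrays, did not pass; they were -0.32 for both without K278*, where both shifts passed with the preset correlation (neither with an estimated one), and turned to 0.07 and 0.08, not passing, without E824*. The shifts of ERK-output (-0.29), DNA repair (-0.12) and hypoxia and glycolysis genes (-0.16) also passed without K278*, with the preset correlation and not with an estimated one. They did not pass with all arrays or without E824* or Q1430*. In simulated data of this design 28% of 2-fold changes were recovered and 92% of 4-fold changes, so a difference of 2-fold or less would often have been missed. The simulated groups had equal spread, unlike these arrays, so the recovery at 4-fold need not hold here.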

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

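The tests that set the wild-type GFP and K278* arrays against the other wild-type-line arrays were chosen only after the result was seen. Those on chromosomes, second probe sets, reconstitution, splits and neighbouring genes were set out before theirs.

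For 5 of 32 gene lists the mean level of the wild-type GFP array lay far from those of the other 5 wild-type-line arrays, which carry different constructs and are not 1 labelled group; the values are its gap to the nearest array over the whole range. The GFP array was lowest for imprinted genes (0.649), secreted factors (0.635), the unfolded-protein response (0.697) and Wnt, BMP and TGF-beta genes (0.734), and highest for NRF2 genes (0.67). Chance flags about 1 list in 20, and lists share arrays, so these flags are not independent.

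The GFP array stands apart, and K278* lies between it and the other 4 wild-type-line arrays. K278* differed by more than 2-fold from full-length PREX2 at 143 probe sets, and from LacZ, Q1430* and E824* at 258, 362 and 648. Full-length PREX2 and E824* differed at 153, so setting GFP and K278* against the other 4 is a choice. Cells of the null line mixed into the GFP and K278* cultures were argued against, since 4 genes that were bright in the null line and at 1% or less on the other 4 arrays (C1qtnf3, Cdkn2a, Hoxc8 and Zmpste24) had a median of at most 0.313% of the null-line signal. The second component, computed without cell-cycle genes, ordered the 6 arrays in exact reverse of the mean of the G1/S and G2/M lists (Spearman's rank correlation -1, exact permutation p = 0.00278; Pearson r -0.968, exact permutation p = 0.00139; r -0.957 without the 2 arrays farthest from the median), so a difference in growth state is a candidate explanation. The means of 9 of the 31 other lists tracked the component nearly as closely, so the test does not single out growth. The actin 3' over 5' ratio, which degradation raises, was at most 1.21 on the GFP and K278* arrays and 1.31 to 1.36 on the other 4. The GAPDH ratio was 0.815 on GFP and 0.901 on K278*, against 0.862 to 0.922 on the other 4, so it did not separate K278*. A difference in RNA quality or labelling stays open, though not as more degraded RNA in the 2.

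The 2 lines differ at 3753 probe sets (1011 to 4522 with 1 array left out). Of the 84 splits, only the real one, all 3 null-line against all 6 wild-type-line arrays, gave as many as 8285 calls, and the highest other gave 0. A mixed split puts the line difference into the spread, and each genotype is 1 line. The splits therefore cannot tell a chance difference between lines from an effect of genotype. Subtracting the median change of each chromosome left 84.7% as many calls (3177, of which 2885 were shared), and a second probe set went the same way in 94.1% of 913 called genes (95% interval 92.4 to 95.5; 73.8% among genes not called; 497 second probe sets were themselves called the same way and 4 the opposite way), against whole-chromosome copy number and sequence variants under the probes as the whole cause. The slope of the reconstitution change on the line difference was -0.031, and 0.002 with the null arrays swapped, so little of that difference was reversed on the 1 reconstituted array. Enzyme activity was not measured here, so the slope does not bound what loss of Suv420h1 accounts for. Changes that set in before reconstitution, and differences between separately immortalised lines, were not tested.

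Cdkn2a and Cdkn2b were near 0 on every wild-type-line array (means of 5.497 and 4.63, against 3839 and 1496 in the null line). A loss reaching the nearest expressed gene on each side is argued against, since Mtap read 119% and Tusc1 575% of the null-line signal on those arrays. A loss of these 2 genes alone or with neighbours dim in the null line too, and silencing without loss, stay open as untested; the wording was narrowed to this after the value was seen.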

How the results depend on the processing

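The arrays left out together with the wild-type GFP array, the covariate, the list shifts without single arrays and the calls made without a null array were chosen after seeing the data. Against the 3753 calls between the lines, 1834 passed with the spread of these groups alone, 8285 with all 3 null-line against all 6 wild-type-line arrays, 1941 with GFP arrays alone, 7054 without the GFP and K278* arrays and 7646 with the cell-cycle mean as a covariate; leaving out single arrays gave 1011 to 4522. The 1 call for truncated PREX2 became 0 with an offset of 100, no filter, the spread of these groups alone, or full-length PREX2 added to the controls, and 3 without the GFP and K278* arrays; leaving out single arrays gave 0 to 117. Over its 16 alternatives the adjusted p of Oas1a ran from 0.00528 to 0.919, and 8 passed, with log2 changes from 1.26 to 2.74, higher in each. For full-length PREX2 leaving out single arrays gave 0 to 3 calls. Reconstitution gave 1 call with quantile normalization, 233 with the spread of these groups alone, 172 without the GFP and K278* arrays and 2 with the covariate. With the spread of these groups alone, the log2 changes were the same as in the main fit (correlation 1). So were those on reconstitution without the wild-type GFP and K278* arrays, which are in neither of its groups. In these settings only the estimated spread and its degrees of freedom moved the calls. Elsewhere fewer arrays and other residual degrees of freedom go with many of the differences in calls, and the cause was not tested.

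List shifts passing with the preset correlation, 8 for truncated PREX2, 11 for full-length PREX2, 6 for truncated against full-length, 6 between the lines and 2 for reconstitution, became 0 in each with an estimated correlation, and 2 for truncated against full-length with quantile normalization. With the preset correlation, leaving out single arrays gave 4 to 14, 2 to 15, 5 to 9, 7 to 11 and 1 to 3. With an estimated one, none then passed for full-length PREX2 or reconstitution. The share of reversal was 51.7% with the null arrays swapped, 54.9% with shared null arrays, and 52.5% and 46.6% with calls made without the other null array. Of the named genes' alternatives 2091 kept direction and side of the threshold, 188 lost and 25 gained a call, and 4 turned, none of a called value: Cdkn2a on reconstitution (-0.16 to 0.192 over null arrays left out) and the brightest Kmt5b probe set between the lines (-0.10 without the GFP control array to 0.532 without LacZ, -0.10 without GFP and K278*, and -0.047 with all arrays by line). Dim probe sets are limited by signal over background.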

Other observations

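The genes, arrays and the shuffling test of this part were all chosen after the data were seen. Of the HOX genes past the threshold in the null line, Hoxc8, Hoxc10, Hoxa9, Hoxa10, Hoxc9 (3.995), Hoxc6 (2.57) and Hoxc4 (1.92) rose, and Hoxb2 (-2.15), Hoxa2 (-1.85), Hoxd8 (-1.65), Hoxa3 (-1.49), Hoxb3 (-1.38), Hoxb4 (-0.98) and Hoxd9 (-0.88) fell (limma, 2 against 2 arrays). Of other transcription factors of the list, Foxd1 (2.07), Msx1 (1.98) and Shox2 (1.72) rose, and Meis1 (-1.91), a HOX cofactor, Prrx2 (-1.72), Lhx9 (-1.27), Twist2 (-1.06), Tbx15 (-0.99) and Tbx18 (-0.70) fell. With either null array left out, 10 of the list rose and 7 fell.

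Among the genes that differed most between the GFP and LacZ control arrays (1 array each, no test) were the following. The proteoglycan Dcn read 962 with GFP and 21523 with LacZ, the matrix protein Ccn3 1415 and 22742, Igf2 13.4 and 835, and Scara5 195 and 3862. The AP-1 gene Fosl1 read 1380.5 with GFP and 150.3 with LacZ, the phosphatase Dusp4 712 and 83.3, and Hmga2 9134 and 1807. On K278* the same genes lay between, with Dcn at 7633, Fosl1 at 539 and Hmga2 at 4693.

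Median changes between the lines differed by chromosome, with an SD of chromosome medians of 0.158 against at most 0.0432 in 1000 shuffles of genes over chromosomes (permutation p = 0.001, the smallest these shuffles can give). Chromosome 8 was highest (median 0.31, 77.3% of 569 genes higher) and chromosomes 18 (-0.29), 15 (-0.28) and 7 (-0.27) lowest. Each null-line array showed the change on chromosome 8 (0.33), and the PREX2 arrays lay between -0.05 and -0.03 there.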
